A study of Mus musculus with 4 samples.

How the data were processed

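Total RNA of unstimulated L929 and NIH3T3 cells, with 2 samples of each line, was measured on Affymetrix Mouse Genome 430 2.0 arrays. Per the labels' protocols, RNA was extracted with Trizol and RNeasy columns, checked by spectrophotometry and on a Bioanalyzer, and labelled with biotin. The deposited table holds 1 intensity per probe set and array, and per the submitters' processing notes these intensities are MAS5 signals. The version of MAS5, its scaling target and the genome build are not given in the sources used here. From the values, the deposited intensities are on a linear scale, their 2% trimmed means differ between arrays, and no detection call was used. Samples were assigned to their line and replicate number from their titles, and all 4 value columns matched the sample labels by name.

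The platform annotation names a gene symbol for part of the 45037 probe sets that are not Affymetrix controls. A unique symbol was found for 34945 probe sets, several symbols for 932 and none for 9160, and the last are unnamed here. The identifiers of 34741 of the singly named probe sets were found in a gene table of assembly GRCm38.p6, which changed 0 symbols. Genes were named only from probe sets with a unique symbol, which gave 18193 genes. Because the array files name no build, coordinates are not printed, and the gene table served only for names, chromosomes and the order of neighbouring genes.

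Each array was scaled to a common trimmed mean that leaves out 2% of the non-control probe sets at each end, which is the kind of scaling MAS5 itself applies. The trimmed means before scaling were 142 and 135 for L929 and 135 and 210 for NIH3T3, and the factors were 1.07, 1.14, 1.13 and 0.726. An offset of 8.01, the 25th percentile of all scaled signals, was added before log2 was taken. Probe sets were tested if both arrays of at least 1 line lay above 17.3, the 40th percentile of the scaled signals. Fold changes on this scale understate the change of dim genes. L929 was compared with NIH3T3 with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with a mean-variance trend and all 4 arrays in the fit. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 with a fold above 1.5, the thresholds of the submitters' design text, which names no test. One value per gene was taken from the tested probe set with the highest mean over the 4 arrays, and adjustment was then made over these 12676 genes. Where a line lay below 17.3 on both arrays, the fold is given as a bound: the brighter line's mean against 17.3, as means of log2 signals, written "at least". Where 1 of a line's 2 arrays lay above it, this is said beside the value, and no fold is given if the line's mean lay below the level. The level of 17.3 is a percentile, not a measured detection limit.

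A total of 36 gene lists with 818 distinct members was fixed, of which 749 had a probe set of their own. The 32 lists with at least 5 tested members were tested with limma's camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 32 lists. The same test with an estimated correlation and fry were run beside it. With an estimated correlation, camera has only the few residual degrees of freedom of 4 arrays, so hardly any list could pass it. Camera asks whether a list differs from the other genes, while fry asks whether its genes move on balance one way and compares them with no other genes. The design, the lists, the named-gene rule and the alternatives below were set before the data were examined, except where stated. Genes named in the text are the 12 called genes with the largest difference in each direction, leaving out clone and predicted-gene names, all members of the necroptosis list with a probe set of their own, up to 3 called members per direction of each other list, and the members of the marker lists. Genes outside this rule are said to be so where they appear.

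The procedure was tested on simulated data for the comparison of L929 with NIH3T3, over 25932 probe sets of which 200 were changed. It recovered 38% of the probe sets changed 1.5-fold, 96% of those changed 2-fold and 100% of those changed 4-fold or 8-fold. The changed probe sets were drawn from genes above the median signal, so the recovery does not cover dimmer genes. Noise was independent between probe sets and had the same spread at a given signal, which real genes need not have. Of 25732 unchanged probe sets, 68 were called, and 60 of these lay in the dimmest 10%. With no filter 0 were called, and with a filter on the mean of all 4 arrays 6 were called, so the filter, which looks at the lines separately, adds calls among dim probe sets. Only 200 probe sets were changed, whereas 31.6% of the tested probe sets were called in the real data. The adjusted p depends on that share, so neither the recovery nor the number of false calls need carry over. The simulated shifted list was called, and 0 of 32 unshifted lists were called. No gene outside the shifted list was changed there, so this does not cover data in which many genes differ.

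Alternatives changed 1 choice at a time: an offset of 1, an offset 4 times larger, a floor in place of the offset, no filter, a stricter filter at the 60th percentile, the values as deposited without scaling, quantile normalization, no mean-variance trend, a test per probe set without moderation, the replicate number as a block, each array left out in turn, a fold above 2, and representative probe sets without the suffixes that mark possible cross-hybridisation. Where an array was left out, the lone array was assumed to vary like the other line. Median scaling, the filter on the mean of all 4 arrays and the antigen presentation list without H2-D1 were added after seeing the data. The difference between replicates was also compared across levels of signal.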

Results

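Gene expression was measured in unstimulated cells of L929, a fibroblast line from mouse connective tissue, and NIH3T3, a fibroblast line from mouse embryos, with 2 arrays per line. The submitters chose L929 as a line prone to necrosis and NIH3T3 as a line prone to apoptosis, so the comparison asks which transcripts differ between lines that tend to die in different ways, before a death signal is given. Because only 1 line stands for each way of dying, no difference can be assigned to the way of dying rather than to the line. Each value is a MAS5 signal in arbitrary units, scaled to a common trimmed mean and given as mean ± SD with n = 2 arrays per line. The median signal as deposited was 23.5 and 24.0 on the L929 arrays and 23.9 and 38.3 on the NIH3T3 arrays, and the trimmed mean of NIH3T3 replicate 2 was 1.55 times that of replicate 1. After scaling, the replicates correlated across tested probe sets with r = 0.982 in L929 and r = 0.981 in NIH3T3, against 0.835 to 0.843 between arrays of different lines. Probe sets are not independent replicates, so these r values only describe the arrays. The actin 3' to 5' signal ratio was 1.22 to 1.23 on all 4 arrays, and the Gapdh ratio was 0.726 to 0.865. Spike-in controls averaged 542 on NIH3T3 replicate 2 and 573 to 676 on the other 3 arrays as deposited, and 394 against 650 to 727 after scaling. The number of arrays limits the precision. The labels do not say that replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

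L929 and NIH3T3 differed in 34.8% of the genes tested, in both directions, and the genes that differed most were bright in 1 line and near background in the other. The genes with the largest excess in L929 were Avil, which encodes the actin-binding protein advillin, Sumo3, a ubiquitin-like modifier, Sncg, or gamma-synuclein, S100a1, a calcium-binding protein, and Crabp2, a retinoic acid carrier. Avil measured 2187 ± 69.9 in L929 and 2.92 ± 1.55 in NIH3T3, at least 127-fold higher (limma adjusted p = 3e-08), and Sumo3 measured 3548 ± 54.7 against 21.9 ± 10.4, a 123-fold difference with 1 of 2 NIH3T3 arrays above the filter level. The remaining genes of the 12 highest were Ripk3, Hoxc10, Pla2g5, Cadm4, Fabp4, Crip2 and Lonrf3. In the other direction, Fstl1, a secreted glycoprotein, measured 0.807 ± 0.141 in L929 and 2975 ± 204 in NIH3T3, at least 172-fold lower in L929, and Lox, the collagen-crosslinking lysyl oxidase, was at least 258-fold lower. The 3 tested Lox probe sets ranged from -8.73 to -2.72 on the log2 scale. The others of the 12 lowest were Marcks, Cd34, Tnc, Ccn2, Tmsb4x, Ckap4, Ubqln2, Crabp1, Ramp3 and Sox4. Crabp1, the paralogue of Crabp2, went the opposite way, from 3146 ± 55.7 in NIH3T3 to 11.8 ± 2.49 in L929, at least 182-fold lower.

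Of 12676 genes tested, 2187 were called higher and 2228 lower in L929, together 34.8%. At 4-fold or more, 401 were higher and 540 lower. Over 27438 probe sets, 4091 were higher and 4582 lower, so that 47.2% of the called probe sets were higher in L929. Without scaling that share was 28.5%, and the median log2 difference of all genes moved from 0.014 to -0.26, because NIH3T3 replicate 2 is brighter as deposited. In the dimmest 10% of the tested probe sets 1015 of 2744 were called, where the simulation placed most of its false calls, and a filter that ignores the lines gave 2036 genes higher and 2107 lower. Probe sets of the same gene were called in opposite directions for 65 of the 5997 genes with several tested probe sets.

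**Figure D1:**
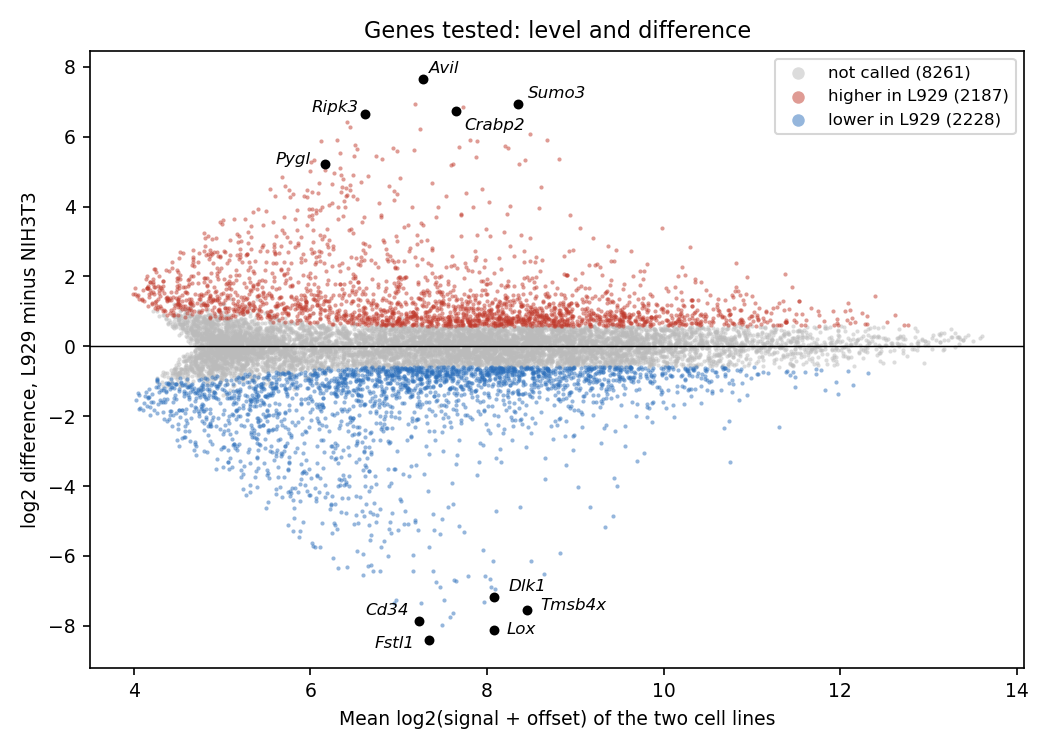
Each point is a tested gene, with the mean log2(signal + offset) of both lines on the x axis and the log2 difference, L929 minus NIH3T3, on the y axis. The 2187 genes higher in L929 are red, the 2228 lower are blue and the rest grey; Avil and Sumo3 lie at the top and Fstl1 and Lox at the bottom.

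The list fixed for the main question held the machinery of necroptosis, the regulated form of necrosis driven by death receptors, and its regulators. Ripk3, the kinase at the centre of the necrosome, was high in L929 and below the filter level in NIH3T3: it measured 978 ± 67.6 in L929 and 1.86 ± 0.0846 in NIH3T3, at least 56.6-fold higher (limma adjusted p = 1e-07). Pygl, the liver form of glycogen phosphorylase, a metabolic enzyme reported to interact with RIPK3, measured 431 ± 32.5 against 3.76 ± 0.498, at least 25-fold higher (adjusted p = 7.2e-07). Parp2, a poly(ADP-ribose) polymerase, was 2.24-fold higher (409 ± 2.73 against 178 ± 1.42, adjusted p = 6e-05). Dnm1l, the mitochondrial fission GTPase, was 1.81-fold lower in L929 (528 ± 20.8 against 960.1 ± 26.9, adjusted p = 1.5e-04). Fas, a death receptor, was dim in both lines, at 3.45 ± 0.048 in L929 and 27.1 ± 10.8 in NIH3T3, at least 1.51-fold lower (adjusted p = 0.0063).

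The 13 other tested members of the necroptosis list were not called. Mlkl, the pore-forming effector that RIPK3 phosphorylates, measured 748 in L929 and 951 in NIH3T3 (log2 difference -0.34, adjusted p = 0.018), a 1.27-fold difference that lay under the fold threshold. Log2 differences of the death receptor complex genes were -0.28 for Tnfrsf1a, 0.32 for Tradd, 0.26 for Fadd, 0.29 for Casp8 and 0.19 for Cyld. The signs of Fadd and Cyld were not settled, as other tested probe sets reached -0.28 for Fadd and -0.54 for Cyld. Cflar, which encodes the caspase-8 regulator FLIP, stood at -0.38, with its probe sets ranging from -0.38 to 1.70. Spata2 stood at 0.50, Glud1 at 0.42, Glul at -0.46, Ticam1 at 0.28 and Pgam5 at 0.00. Bmf stood at -0.28, with 1 of 2 L929 arrays above the filter level. Zbp1 and Tlr3 lay too near background in both lines to be tested, and 2 more members had no probe set of their own and were not analysed here. Ripk1 is not among the 20 members with a probe set of their own, so the list gives no value for it. Thus 3 of 18 tested members were higher and 2 lower, the same counts as adjusted over the list alone, and the list as a whole did not pass the camera test (adjusted p = 0.399, and adjusted p = 0.698 with an estimated correlation). Camera looks for a shift of the list in 1 direction, so it does not decide whether members moved in opposite directions. The fry test, which does not compare the list with other genes, gave an adjusted p of 0.00736. The lower count was 4 without NIH3T3 replicate 1, where Cflar and Glul were also called, and 1 without NIH3T3 replicate 2, where the call of Fas was lost. It was also 1 with the filter on the mean of all 4 arrays, under which Fas was too dim to be tested, whereas Fas was called with no filter; Parp2 was not called without scaling.

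**Figure D2:**
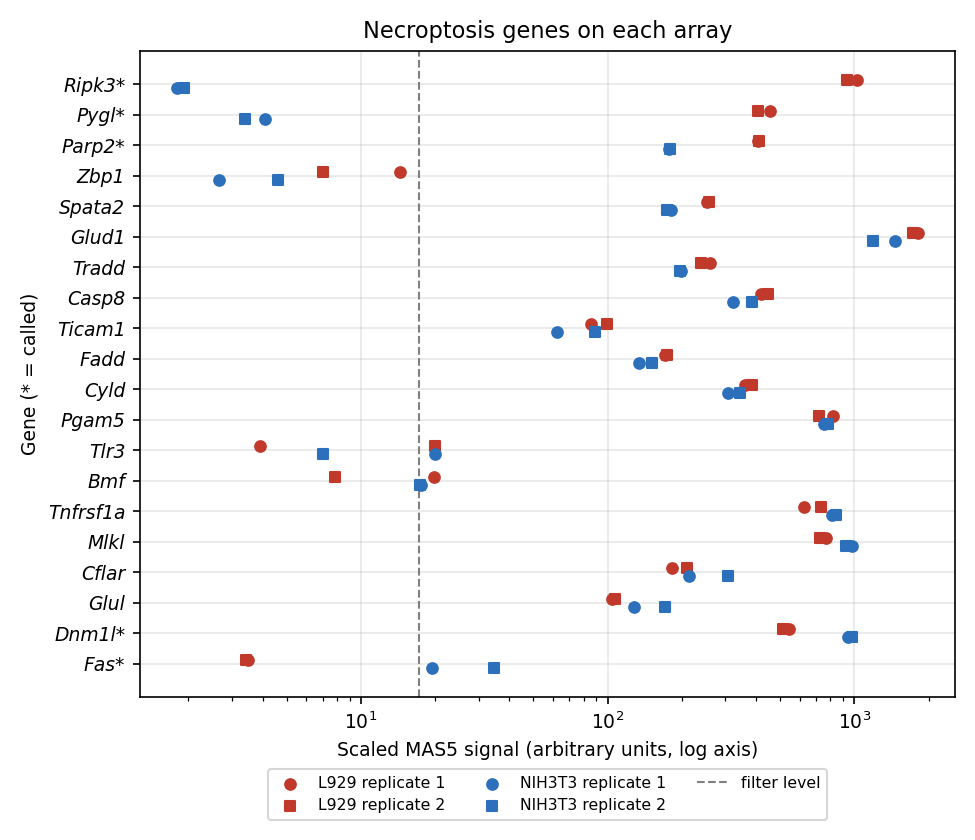
Scaled MAS5 signal (x axis, arbitrary units, log axis) of each necroptosis gene on each of the 4 arrays, with L929 in red, NIH3T3 in blue, circles for replicate 1 and squares for replicate 2. The dashed line is the filter level of 17.3 and called genes carry an asterisk; Ripk3 and Pygl lie left of it on both NIH3T3 arrays and far right of it on both L929 arrays.

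The other death-related lists, described next, held called genes in both directions, and 0 of these 6 lists passed the camera test of limma, 1 had an unadjusted p under 0.05, and 4 passed with fry. In the BCL-2 family 5 of 14 tested genes were higher and 1 lower (adjusted p = 0.0827): Bid, the BH3-only protein cleaved by caspase-8, was 6.79-fold higher in L929 at 1822 ± 24.5 against 263.7 ± 47.9, while Bnip3, a mitochondrial BH3-type protein, was 3.56-fold lower. This list passed in 3 of 16 alternatives, without NIH3T3 replicate 2 (adjusted p = 0.0434), with the stricter filter (0.0445) and with no filter (0.0483), within a range of 0.0434 to 0.233. Among caspases and apoptosome genes 6 of 19 were higher and 1 lower (adjusted p = 0.417), led by Casp1, the inflammasome caspase, at 245 ± 10.9 against 3.47 ± 1.92, at least 14.2-fold higher. Without L929 replicate 2 only 3 caspase-list genes were higher, and the lower count was 2 without L929 replicate 1 and 3 without NIH3T3 replicate 1. Of 27 genes of the TNF receptor complex and NF-kB kinases 4 were higher and 1 lower (adjusted p = 0.646). Traf2, an adaptor of the TNF receptor complex, was 2.20-fold higher, a call lost without scaling, and Birc3, the ubiquitin ligase cIAP2, was at least 6.48-fold lower; 2 were lower without L929 replicate 1 or with the replicate block, and 3 without L929 replicate 2. Of 12 other death ligands and receptors 1 was higher and 4 were lower (adjusted p = 0.573), among them Cd40, 4.45-fold higher with 1 of 2 NIH3T3 arrays above the filter level, and Eda2r, at least 2.44-fold lower. That list had 2 higher genes without NIH3T3 replicate 1 and 2 lower ones without NIH3T3 replicate 2.

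Genes commonly induced through NF-kB split, with 7 of 16 higher and 5 lower (adjusted p = 0.735). Csf1, the macrophage growth factor, was 3.92-fold higher in L929, at 3904 ± 30.9 against 991 ± 53.9, and the chemokine Cxcl1 was 3.83-fold higher. The chemokine Cxcl5 was at least 40.8-fold lower and Ptgs2, the inducible cyclooxygenase, was 29.0-fold lower, at 119.7 ± 12.2 against 3697 ± 428. The median of this list was 0.49 and its mean -0.49, while camera gave it an upward direction. Of 19 p53 target genes 5 were higher and 9 lower (adjusted p = 0.164), with Gadd45a 2.78-fold higher, and Zmat3 and Ccng1 8.61-fold and 4.04-fold lower in L929.

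Matrix glycoprotein and contractile cytoskeleton genes were more often lower than higher in L929, and collagens more often higher than lower. Of 27 matrix glycoproteins, proteoglycans and crosslinking enzymes 14 were lower and 3 higher, or 15 lower and 3 higher adjusted over the list alone, and the list passed the camera test (adjusted p = 6.7e-04, but adjusted p = 0.386 with an estimated correlation). Lox measured 4473 ± 540 in NIH3T3 and 8.37 ± 4.91 in L929, the matrix protein tenascin C, Tnc, was at least 158-fold lower and the matricellular factor Ccn2 at least 156-fold lower, whereas Tgfbi, a matrix adhesion protein, was 13.5-fold higher. Contractile and SRF target genes were lower for 11 of 17 members and higher for 2 (adjusted p = 0.0029, and adjusted p = 0.386 with an estimated correlation). Acta2, smooth muscle actin, measured 52.3 ± 28.6 in L929 and 3440 ± 295 in NIH3T3, a 60.6-fold difference, and Tagln, or transgelin, was at least 58.9-fold lower. Of 18 collagens 9 were higher and 1 lower, or 9 and 2 adjusted over the list alone, without passing the list test (adjusted p = 0.0705). Col5a3 was 15.9-fold higher in L929, Col4a1 2.77-fold higher and Col4a5 12.7-fold lower. The collagen list would pass without NIH3T3 replicate 1 (adjusted p = 0.0383) or without NIH3T3 replicate 2 (0.0473), within a range of 0.0383 to 0.104 over the settings at the preset correlation (adjusted p = 0.386 with an estimated correlation), and 2 collagens were lower without L929 replicate 2 or NIH3T3 replicate 2, with quantile normalization, with the replicate block and with the filter on the mean of all 4 arrays, where 8 were higher. Matrix proteases and their inhibitors, with 3 higher and 9 lower of 18, also missed the threshold (adjusted p = 0.0705). Mmp2, gelatinase A, was 24.1-fold lower and Ctsk, cathepsin K, 20.5-fold higher with 1 of 2 NIH3T3 arrays above the filter level. The protease list passed in 7 of 16 alternatives, within a range of 0.0300 to 0.147: without scaling (0.0300), with quantile normalization (0.0379), median scaling (0.0452), the stricter filter (0.0445) or the filter on the mean of all 4 arrays (0.0441), and without L929 replicate 2 (0.0431) or NIH3T3 replicate 2 (0.0473).

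Fibroblast identity and adhesion genes were also lower in L929 on balance. Of 21 fibroblast and mesenchymal identity genes 10 were lower and 3 higher (adjusted p = 0.0127, and adjusted p = 0.386 with an estimated correlation). Thy1, a surface marker of fibroblasts, measured 24.0 ± 8.5 in L929 and 2223 ± 41.9 in NIH3T3, a 70.9-fold difference, and the transcription factor Osr1 was at least 51.2-fold lower, while Snai2 was 5.06-fold higher; 5 were higher without NIH3T3 replicate 1. Integrins, cadherins and adhesion receptors were lower for 8 of 18 and higher for 3 (adjusted p = 0.0233, and adjusted p = 0.386 with an estimated correlation). Cd34 was at least 132-fold lower and Cdh2, N-cadherin, at least 54.9-fold lower, and the integrin subunit Itgb5 was 2.64-fold higher. The adhesion list lost its call without NIH3T3 replicate 1 (adjusted p = 0.0518), the highest of its range from 4.0e-07.

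Growth factor and Wnt pathway genes were lower in L929 on balance. Of 28 growth factors and receptor kinases 15 were lower and 4 higher, or 15 and 5 adjusted over the list alone (adjusted p = 0.0034, and adjusted p = 0.386 with an estimated correlation). The platelet-derived growth factor Pdgfc was 31.0-fold lower, the receptor Met 9.09-fold lower and its ligand Hgf at least 17.2-fold lower in L929, and the insulin-like growth factor binding protein Igfbp4 was 7.13-fold higher. Only 2 genes of this list were higher without L929 replicate 2, NIH3T3 replicate 1 or NIH3T3 replicate 2. Wnt pathway genes were lower for 7 of 19 and higher for 2 (adjusted p = 0.0372, and adjusted p = 0.386 with an estimated correlation). The Wnt receptors Fzd1 and Fzd2 were 24.2-fold and at least 52.6-fold lower, and the ligand Wnt5b was at least 3.57-fold higher. The Wnt call was lost without NIH3T3 replicate 1 (adjusted p = 0.0502) or NIH3T3 replicate 2 (0.0504) and with an offset of 1 (0.0539), the highest of its range from 3.7e-05. TGF-beta and BMP genes, with 11 of 26 lower and 4 higher, did not pass (adjusted p = 0.0842). The BMP antagonist Grem1 was 25.3-fold higher in L929, at 823.5 ± 12.9 against 25.1 ± 5.99, and Tgfbr3 was 3.19-fold lower. That list passed without L929 replicate 1 (adjusted p = 0.0376) and with no filter (0.0483), within a range of 0.0376 to 0.346.

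HOX genes were more often higher than lower in L929, and imprinted genes more often lower. Of 24 tested HOX genes, the transcription factors of body-axis position, 13 were higher and 1 was lower (adjusted p = 0.0054, and adjusted p = 0.386 with an estimated correlation). Hoxc10 measured 781.5 ± 153 against 1.15 ± 0.79, at least 44.9-fold higher, Hoxa9 was at least 49.4-fold higher and Hoxa10 at least 19.9-fold higher. The lower call, Hoxa3 at 46.7 ± 3.01 against 77.9 ± 4.87, was lost when any 1 of the 4 arrays was left out, with quantile normalization and with the replicate block, and 3 HOX genes were lower without L929 replicate 2. Of 11 imprinted genes 8 were lower and 0 higher (adjusted p = 6.4e-04, and adjusted p = 0.386 with an estimated correlation). Dlk1, a Notch-family ligand, measured 15.4 ± 12.6 in L929, where 1 of 2 arrays lay above the filter level, and 3133 ± 147 in NIH3T3, and its other tested probe set differed by -1.75 on the log2 scale. Grb10, a receptor adaptor, also above that level on 1 of 2 L929 arrays, was 101-fold lower, and Plagl1, a zinc finger factor, was at least 22.7-fold lower, although another Plagl1 probe set differed by only -0.05. The 3 tested Grb10 probe sets ranged from -6.65 to -2.71 on the log2 scale. Without NIH3T3 replicate 1, 2 imprinted genes were called higher.

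Genes of the unfolded protein response were more often higher than lower in L929 and gave the lowest p of the lists. Of 26 tested members 17 were higher and 1 lower (adjusted p = 5.8e-06, but adjusted p = 0.386 with an estimated correlation), with a median log2 difference of 0.75. Trib3, a pseudokinase induced by ATF4, was 5.59-fold higher, at 923 ± 53.6 against 158.9 ± 18.2. Sdf2l1, an endoplasmic reticulum chaperone cofactor, was 5.31-fold higher and the disulfide isomerase Pdia4 3.57-fold higher. The lower member was the stress factor Atf3, at 3.60 ± 0.665 against 27.8 ± 11.7, its call was lost without NIH3T3 replicate 2, and it was too dim to be tested with the filter on the mean of all 4 arrays. Respiratory chain and ATP synthase genes were higher for 5 of 27 members and lower for 0, with a median of 0.32, or 0.49 without NIH3T3 replicate 1 (adjusted p = 0.0053 with all 4 arrays, but adjusted p = 0.603 with an estimated correlation). Uqcrfs1, the Rieske protein, was 1.73-fold and Sdha, a succinate dehydrogenase subunit, 1.72-fold higher, and neither was called without scaling. The respiratory chain list lost its call without L929 replicate 1 (adjusted p = 0.0547) and without scaling (0.206), the highest of its range from 3.5e-06. The brightest 1% of the tested probe sets were lower on NIH3T3 replicate 2 than on replicate 1, by a median log2 difference of -0.58, against -0.10 between the 90th and 99th percentiles of signal and 0.01 to 0.04 below the 90th. Between the L929 replicates the brightest 1% differed by a median of 0.00097. The respiratory chain genes differed between the NIH3T3 replicates by a median of -0.13 and the unfolded protein response genes by 0.03.

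Cell cycle genes were higher for 10 of 34 members and lower for 2 (adjusted p = 0.0233, and adjusted p = 0.498 with an estimated correlation). Cdk2 was 6.77-fold higher in L929, at 424 ± 12.8 against 55.9 ± 5.99, Ccnb2, a mitotic cyclin, was 5.03-fold higher, and the cell cycle inhibitor Cdkn1a was 2.84-fold lower. The call of this list was lost without NIH3T3 replicate 2 (adjusted p = 0.0545), with quantile normalization (0.0604) and without scaling (0.145), the highest of its range from 0.00552. Lysosome and autophagy genes were lower for 11 of 26 and higher for 3 (adjusted p = 0.0204, and adjusted p = 0.498 with an estimated correlation). Gla, the lysosomal alpha-galactosidase, was 5.21-fold lower and Map1lc3a, an autophagosome protein, 2.69-fold lower, and Ctsz, a lysosomal protease, was 1.95-fold higher, a call lost without scaling. The lysosome call was lost without NIH3T3 replicate 1 (adjusted p = 0.0537) and without scaling (0.0680), the highest of its range from 0.0052. Cholesterol synthesis and uptake genes were lower for 7 of 20 and higher for 1 (adjusted p = 0.0484, and adjusted p = 0.386 with an estimated correlation). Stard4, a sterol transfer protein, was 31.4-fold lower and Nsdhl, a sterol dehydrogenase, 3.01-fold lower, while Cyp51, lanosterol demethylase, was 2.46-fold higher. This list lay at the threshold, with a range of 0.0218 to 0.0788, its call being lost in 7 of 16 alternatives, and 2 of its genes were higher without L929 replicate 1 or NIH3T3 replicate 2.

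Glycolysis, antioxidant and NADPH oxidase lists did not pass. Of 16 glycolysis genes 3 were higher and 4 lower, or 3 and 5 adjusted over the list alone (adjusted p = 0.487). Isoforms differed within the pathway: Pfkp, the platelet-type phosphofructokinase, was 13.7-fold higher in L929 and Pfkm, the muscle type, 2.73-fold lower, and the lactate dehydrogenase subunit Ldhb was 4.83-fold lower. Of 29 antioxidant genes 7 were higher and 3 lower (adjusted p = 0.284). Sod3, the extracellular superoxide dismutase, was 16.1-fold higher, the glutathione transferase Gstm2 15.5-fold higher, and Nqo1 and catalase, Cat, 2.56-fold and 2.54-fold lower. The antioxidant list passed without NIH3T3 replicate 1 (adjusted p = 0.0495), within a range of 0.0495 to 0.582. Among 5 NADPH oxidase genes 1 was lower, Cyba, the p22phox subunit, at 54.8 ± 5.74 against 636 ± 5.79, a 10.3-fold difference (adjusted p of the list = 0.846). The list had a median of 0.12 but a mean of -0.37, and camera gave it a downward direction; the median was 0.32 without NIH3T3 replicate 1 and -0.07 without NIH3T3 replicate 2.

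**Figure D3:**
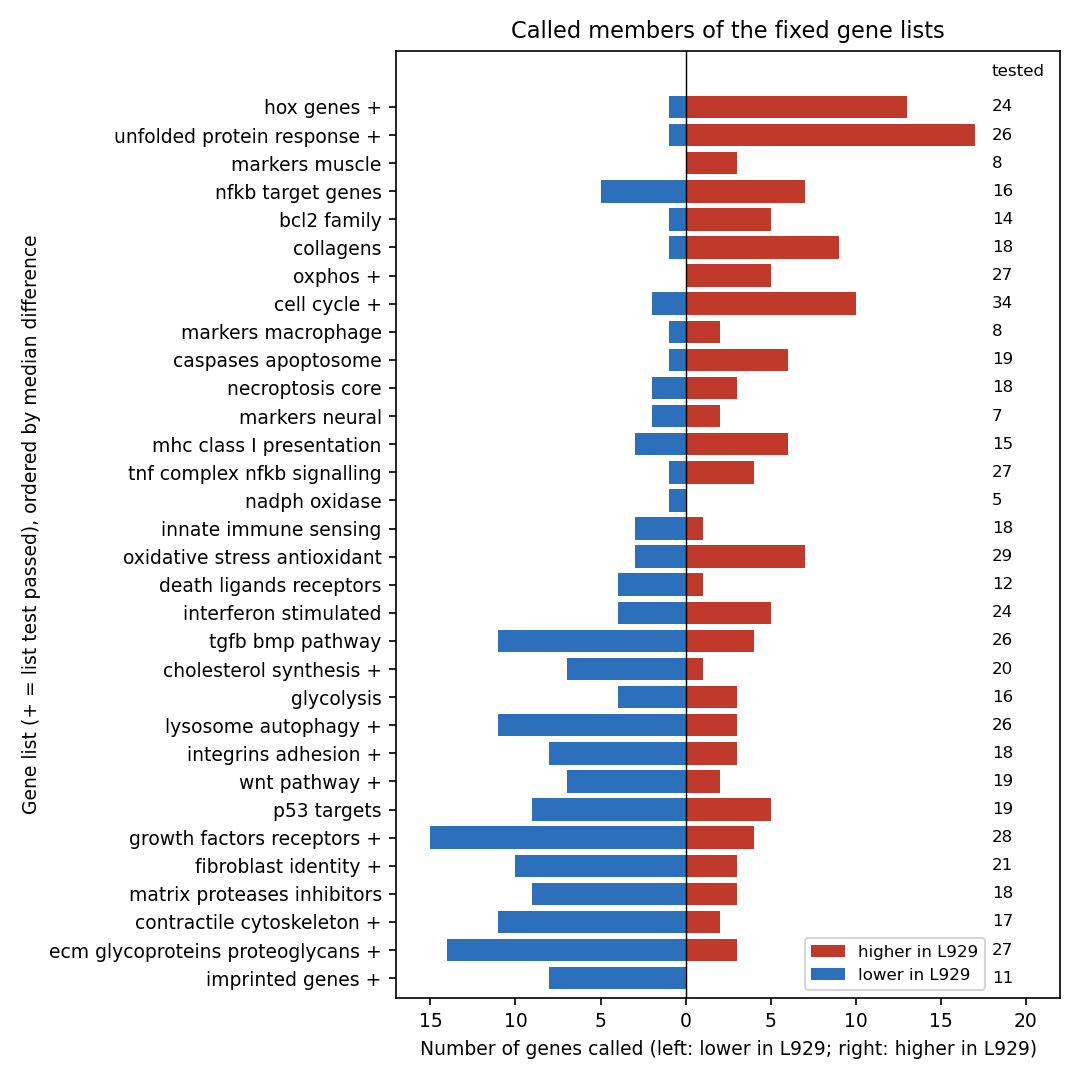
Number of genes called in each of the 32 tested lists (x axis, number of genes), to the right for higher and to the left for lower in L929, with the number of tested genes at the right edge and lists ordered by their median difference. A plus marks the 13 lists that passed camera at the preset correlation; the unfolded protein response has 17 higher genes and 1 lower, and the imprinted genes 8 lower and 0 higher.

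Of 74 markers of other cell types with a probe set 39 were not tested and 21 not called, while 11 were higher and 3, Cd68, Snap25 and Tubb3, lower in L929. Of 4 tested adipocyte markers 3 were higher and 0 lower. Pparg, the adipogenic nuclear receptor, Fabp4, a fatty acid carrier, and Lpl, lipoprotein lipase, were the higher ones, and Retn, resistin, was not called (27.0 ± 5.03 against 40.9 ± 13.6). Adipoq, Cebpa, Cidec, Cd36 and Lep were too dim to be tested, with means of 11.2, 10.7, 6.48, 5.57 and 1.59 in L929 and 11.5, 4.81, 6.12, 11.3 and 0.635 in NIH3T3. Fabp4 measured 2953 ± 163 against 35.7 ± 1.84, a 67.8-fold difference, Pparg was at least 22.7-fold and Lpl 23.5-fold higher. The 4 tested Fabp4 probe sets ranged from 1.07 to 6.08 on the log2 scale. Of 8 skeletal and cardiac muscle markers 3 were higher and 0 lower (adjusted p = 0.105, and 0.0144 without scaling), led by Tnnt2, cardiac troponin T, at least 24.1-fold higher. Of 8 macrophage and leukocyte markers 2 were higher and 1 lower (adjusted p = 0.597), among them Coro1a, a leukocyte actin regulator, higher at 194 ± 4.0 against 13.1 ± 8.84 with 1 of 2 NIH3T3 arrays above the filter level. The other macrophage marker calls, Lyz2 and Cd68, were lost without L929 replicate 2, and that of Lyz2 also without NIH3T3 replicate 2 and that of Cd68 without NIH3T3 replicate 1. Of 7 neural markers 2 were higher and 2 lower (adjusted p = 0.846), with S100b at least 13-fold higher and Snap25 at least 2.06-fold lower, and 1 was higher without L929 replicate 2 or NIH3T3 replicate 1. Both lower neural markers, Snap25 and Tubb3, were too dim to be tested with the filter on the mean of all 4 arrays, which left 2 higher and 0 lower of 5, and were called with no filter. Among 4 endothelial markers 1 was higher, the TGF-beta co-receptor endoglin, Eng, at 1113 ± 39.7 against 26.2 ± 22.4 with 1 of 2 NIH3T3 arrays above the filter level, and 2 were higher and 1 was lower without NIH3T3 replicate 2. Of 4 epithelial markers and 1 sex-chromosome gene tested, 0 were called.

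Of the 13 lists that passed camera, 4 were higher and 9 lower in L929, and 0 held with an estimated correlation, where the lowest adjusted p was 0.386. The matrix glycoprotein list failed there although its estimated correlation, -0.034, lay below the preset 0.01. With 4 arrays and so low an estimate, failure with an estimated correlation therefore does not decide whether a list holds. Estimates of the lists that passed ranged from -0.071 for imprinted genes to 0.340 for the respiratory chain. At the higher estimates, members that vary together may also have contributed to the failure, most of all for the respiratory chain. With fry 27 of the 32 lists passed. A test per gene without moderation called 1310 of the 4415 genes in the same direction. Counts adjusted over the list alone were the same as those over all genes for the lists where no second count is given.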

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

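Median scaling, the filter on the mean of all 4 arrays and the antigen presentation list without H2-D1 were chosen after seeing the data; the other alternatives were planned. Of the 4415 called genes, 3748 to 3860 were called in the same direction with an array left out, 4228 with quantile normalization, 4138 with the filter on the mean of all 4 arrays, 2425 without scaling and 1310 in the plain test, and 4 were called in the opposite direction with other representative probe sets. Counts of probe sets or genes moved by over 1.5 times in 3 settings. Without scaling, 1484 probe sets and 796 genes were higher in L929, since NIH3T3 replicate 2 is brighter as deposited. A plain test per probe set without moderation called 703 probe sets higher and 751 lower, or 670 genes higher and 647 lower. With a fold above 2, 2403 probe sets were higher and 2892 lower, or 1269 genes higher and 1369 lower, by construction. With an array left out, probe sets higher ranged from 3490 to 3818 and lower from 3675 to 4391, genes higher from 2003 to 2153 and lower from 1958 to 2249. The necroptosis list then had an adjusted p of 0.249 to 0.673, and 12 to 14 of the other lists passed. Of the other lists 13 passed in the reported test, 0 with an estimated correlation and 26 with fry, and fry also passed the necroptosis list (0.00736).

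Among the lists and the named genes followed here, directions turned only where nothing was called, and the cause was not tested. Without scaling, the log2 difference of Cyld was -0.088, of Fadd -0.017 and of Pgam5 -0.28, and the NF-kB target (adjusted p = 0.302) and interferon lists (0.746) turned; with quantile normalization Pgam5 was at -0.0081. The death ligand list turned with the stricter filter (0.808), the NADPH oxidase list without the trend (0.904) and with other representative probe sets (0.956), and the NF-kB target list with fry (0.0647). With an array left out, Pgam5 ranged from -0.088 to 0.088, Bmf from -0.28 to 0.13, the interferon list from 0.666 to 0.923 and the NADPH oxidase list from 0.466 to 0.769. Among 182 genes named or eligible to be named, 90 lost their call in at least 1 setting, most often in the plain test (80) and without scaling (31). Replicate numbers did not pair the arrays, as deviations of same-numbered arrays correlated at 0.0138; with the replicate block 4153 probe sets were higher and 4681 lower, 4335 of the 4415 called genes were kept, and the cholesterol list was the 1 list whose call was lost (0.0571). Signals near background limit the precision, since 37.0% of the dimmest 10% of tested probe sets was called with the reported filter, and 3619 probe sets were higher and 4050 lower without it.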

Other observations

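The tests on neighbouring genes of chromosome 5 were chosen after the result was seen, as were the count without H2-D1, the comparison of replicates by brightness, the search over windows and the genes named in this part by their position. Immune genes were called in both directions, and 0 of 3 immune lists passed limma's camera, 0 at an unadjusted p under 0.05 and 1 with fry. Of 24 interferon-stimulated genes 5 were higher and 4 lower in L929, or 5 and 5 adjusted over the list alone (limma camera adjusted p = 0.846), with the antiviral enzyme Oas1a higher at 97.4 ± 12.5 against 16.5 ± 12.3, 1 of 2 NIH3T3 arrays lying above the filter level, and Ifit2 3.62-fold lower. Without either L929 array 3 interferon-stimulated genes were higher. Among 18 innate immune sensing genes, which are Toll-like receptors, adaptors and cytosolic sensors, 1 was higher, the adaptor Myd88 at 2.02-fold, a call lost without scaling, and 3 were lower (adjusted p = 0.646), the co-receptor Cd14, 4.23-fold, the DNA sensor Cgas, 2.69-fold, and the kinase Irak2, 2.29-fold lower; 2 were higher without NIH3T3 replicate 2. The median of that list was 0.05, with no stable sign, as it ranged from -0.09 without L929 replicate 2 to 0.14 without L929 replicate 1, and its mean was -0.21. Of 15 genes of MHC class I and antigen processing 6 were higher and 3 lower (adjusted p = 0.380, and 0.00502 with fry), with Cd74, the invariant chain of MHC class II, 11-fold higher, the immunoproteasome subunit Psmb8 at least 5.82-fold higher and the proteasome activator Psme1 2.31-fold lower. H2-D1 gave no settled direction, as its 8 tested probe sets ranged from -4.18 to 6.61 on the log2 scale. Those of H2-K1, a gene outside the naming rule, ranged from -3.73 to 2.20. H2-D1 is 1 of the 3 lower calls, and without it 6 of 14 genes of the list were higher and 2 lower (adjusted p = 0.137, and 0.00533 with fry).

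Mtap, which encodes the methionine salvage enzyme methylthioadenosine phosphorylase and was chosen after its values were seen, measured 34.6 ± 0.133 in L929 and 3059 ± 486 in NIH3T3, a 71.4-fold difference, and its 4 probe sets ranged from -8.45 to -5.56. On assembly GRCm38.p6 its 2 nearest tested neighbours on each side were not called, with log2 differences of 0.61 for Ifna5, 0.39 for Ifnz, -0.23 for Zfp352 and -0.01 for Elavl2. Mean signals of these 4 lay between 20.4 and 103. Of the 20 nearest tested neighbours, 10 on each side, 9 were lower and 2 higher, among them on the side of Ifnz Mllt3, 15.5-fold lower, Rps6 at -1.73, Dennd4c at -1.42, Klhl9 at -1.25 and Focad at -0.82, and on the other side Ift74 at -0.92 and Plaa at -0.85. Among all 766 genes placed on chromosome 4, 22.5% were lower and 16.8% higher. Cdkn2a, the nearby cell cycle inhibitor gene, lay below the filter level in both lines, at 3.03 ± 1.74 and 8.02 ± 1.47, so no difference can be given. Along the genome, windows of 20 neighbouring tested genes were set against 1000 shuffles of the genes' values. The lowest window, Gpr180 to Clybl on chromosome 14, had a median of -1.21 with 13 genes lower and 0 higher, and 4 of 1229 windows lay below the level of -0.84 that 95% of shuffles stayed above. Among these were Akna to Nfib at -1.04 and Fggy to Pde4b at -0.85, both on chromosome 4, the chromosome of Mtap. Fggy is also 1 of the 20 neighbours of Mtap counted above.

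Ripk3 was near background in NIH3T3. A deletion that extends to neighbouring genes would lower these in NIH3T3 as well. The 3 tested genes on each side had a median log2 difference of -0.82, with a median absolute deviation of 1.50, so they were not lower in NIH3T3 as a group. This argues against a deletion of most of these genes, but the median cannot show one that reaches only a few. Mean NIH3T3 signals were 247 for Nfatc4, 323 for Nop9 and 360 for Dhrs1. Cideb, Khnyn and Nynrin, at 29.0, 48.2 and 41.0, were too dim in NIH3T3 to show much. A deletion inside Ripk3, or a silent promoter, may be the cause and was not tested. A sequence variant under the probes cannot be told apart from low expression, because only 1 probe set names Ripk3. Whether the Ripk3 difference is biological therefore stays open. The same limit applies to other genes with 1 tested probe set, such as Avil, Crabp2 and Cd34.

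In L929, 17 of 26 unfolded protein response genes were higher and 1 lower (limma camera adjusted p = 5.8e-06, and adjusted p = 0.386 with an estimated correlation), and 5 of 27 respiratory chain genes were higher and 0 lower (adjusted p = 0.0053, and adjusted p = 0.603 with an estimated correlation). The brightest 1% of tested probe sets were lower on NIH3T3 replicate 2 than on replicate 1, by a median log2 difference of -0.58, and such a compression of bright signals could have lowered abundant transcripts there. Without that array the list medians, less the median of all genes, were 0.829 for the unfolded protein response against 0.741 with it, and 0.321 for the respiratory chain against 0.302. Before that subtraction the respiratory chain median was 0.293 without that array and 0.316 with it. Its centred value rose because the median of all genes moved from 0.014 to -0.028, over 13316 tested genes in place of 12676. For the respiratory chain both values argue against the compression as the whole cause. The unfolded protein response genes were not lower on that array, with a median difference of 0.03 between the NIH3T3 replicates. Leaving the array out could therefore hardly have lowered their value. The respiratory chain value still varied with the arrays and the scaling. It was 0.535 without NIH3T3 replicate 1, where replicate 2 alone stood for NIH3T3. With quantile normalization, which changes all 4 arrays, it was 0.192. A difference between the lines, in culture state or genotype, stays open and was not tested.

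The highest window of neighbouring genes, Cdk6 to Sri on chromosome 5, had a median log2 difference of 1.60, with 15 of 20 genes higher in L929 and 1 lower, Fzd1 at -4.59. Examples are Gatad1, 4.07-fold higher, Ankib1, 5.11-fold higher, and Gtpbp10, at least 31.0-fold higher. The tests argue against chance placement, as 0 of 1000 shuffles gave so high a window and the highest reached 1.10, and against 1 array being out of place, as the lowest median with an array left out was 1.51. More copies of the region in L929 are a candidate explanation that was not tested, since DNA was not measured. They cannot be told apart from a regulatory difference over the region. The window was picked as the highest, so its 15 higher genes are no evidence for extra copies. Cyp51, the cholesterol gene that was called higher, the Wnt receptor gene Fzd1 and the cell cycle gene Cdk6, called 3.14-fold higher, all lie in this window. The excess was not limited to it. Of 1229 windows 6 lay above 0.774, the level that 95% of shuffles stayed below, all on chromosome 5 or 3. Those on chromosome 5 included Fzd1 to Elapor2, which overlaps the window from Cdk6 to Sri, with a median of 1.10. Another was Fam185a to Kcnh2, with 0.90 and 15 of 20 genes higher.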
